A study of Mus musculus with 8 samples.

How the data were processed

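Hippocampal RNA of BALB/c mice was measured on 8 arrays in 4 groups of 2. The groups were undefeated mice given water, defeated mice given water, defeated mice given kososan extract at 1 g/kg and defeated mice given milnacipran at 60 mg/kg, all dosed by mouth each day over 26 days. Samples were grouped by their titles. For the kososan samples the titles and source names say defeated while the field for social condition says undefeated, and the titles were followed. The labels number the samples of a group but do not say that each came from its own animal. The column names give each array its own code, which is not explained. The choroid plexus gene Ttr differed by -6.8 log2 within the undefeated water pair and by 5.69 within the defeated one (first minus second array). In both pairs 11 of 11 other choroid plexus genes above the median level shared its sign. This argues against repeats of 1 RNA in the water groups, but does not show separate animals. The p-values measure the spread between these samples, which may be technical in the treated groups.

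Per the labels and the series' design text, the RNA was amplified with a 3' kit that starts from the poly(A) end, hybridised to the GeneChip MG-430 PM array for the mouse genome and analysed with Affymetrix Expression Console. The deposited values are intensities on a linear scale, already summarised per probe set by the authors. The summarisation algorithm, its settings and any filter are not given in the sources used here. The deposited quartiles were nearly equal on the 8 arrays, with medians from 14.85 to 15.31, so the values look scaled between arrays before deposit, which the sources do not state. Scaling of that kind would remove any change shared by all genes. The lowest intensity on an array lay between 3.84 and 3.95, and a gene near that floor shows a smaller fold change than its RNA had. Of the deposited tables, the second repeats the intensities of the first and adds group averages, which equal the means of the 2 arrays and were not used further. The number of arrays limits the precision of every value.

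Intensities were converted to log2 with no further normalization and no pseudocount. Of 45141 probe sets, 28898 were paired with 1 gene symbol by the platform annotation, 551 with several and 15692 with none listed there. Only those with 1 symbol entered the main comparisons. The Entrez identifiers of 28689 of them were found in the RefSeq gene table, and 0 symbols changed through it. Each gene was represented by its probe set with the highest mean over all arrays, which left 17097 genes. No coordinates are given, because the files name no genome build.

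Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) in a single model of all 8 arrays, with 4 residual and 4.75 prior degrees of freedom, two-sided and with Benjamini-Hochberg adjustment over all genes at 0.05. The comparisons were defeated against undefeated mice given water, each treatment against defeated mice given water, the 2 treatments against each other and each treatment against undefeated mice, with a moderated F test over the groups. A list of 30 gene sets was fixed before the data were examined. It covers the transmitter systems, cytokines and chemokines that the series names, stress and activity genes, and markers of the cell types and neighbouring tissues that a hippocampal dissection could hold. Of its 746 entries 658 were measured. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a comparison. Camera with a correlation estimated from the residuals and fry, which asks whether a list's genes move on balance one way, were run beside it. Correlations of effects across genes were set beside unchanged groups simulated with the same shared control arrays, over 100 draws with independent genes and 1000 draws that mixed the residuals of the real arrays.

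The genes named in the text were chosen by a rule fixed before the data were examined. In the comparisons of social defeat, kososan and milnacipran it takes up to 12 genes per direction that passed the test, and fills up to 12 with the genes of the largest absolute moderated t among genes above the median level whose arrays did not overlap between the groups. From each list that was called it adds the 2 members with the largest absolute moderated t among members above the median level, so dimmer members with larger t are not named by it. Predicted genes without a regular symbol are not named. Members that passed an adjustment over their list alone are named as such. Genes named outside the rule are said to have been chosen after their values were seen.

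The fit was tested on simulated data with the real gene means, gene variances as shrunken by limma toward its trend, and independent genes. All changed genes lay above the median level. For the kososan comparison over 17097 genes, 73 of 100 genes changed 1.5-fold and 100 of 100 genes changed 2-fold were called, with 14 calls among 16897 unchanged genes. For milnacipran, where nothing was changed in that simulation, 0 genes were called. Shrinkage lowers the variance of the most variable genes, so the shares called may be too high for these. They do not describe genes below the median level. All changed genes were altered in the same simulated data, which eases the Benjamini-Hochberg threshold. The shares may thus be too high where few genes change, and 0 calls in a real comparison do not exclude changes of 2-fold. Alternatives changed the variance prior, the choice of probe sets, the level filter, the normalization, array weights, the arrays in the fit and the list test, added the replicate number as a block, and left out each array in turn. An array left alone in its group was then assumed to vary like the other groups. Fits with the mean of the choroid plexus list or of the cortex and subiculum list as a covariate were added after the data had been seen.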

Results

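Gene expression was measured in the hippocampus of BALB/c mice on 8 oligonucleotide arrays. Social defeat, in which a mouse is repeatedly attacked by an aggressor, is a stress model of depression-like behaviour. Kososan is a formula of Japanese herbal (Kampo) medicine, and milnacipran is an inhibitor of serotonin and noradrenaline reuptake. Each of the 4 groups had 2 arrays: water without defeat, water with defeat, kososan with defeat and milnacipran with defeat. Median intensities ran from 14.85 to 15.31 over the 8 arrays. The undefeated water arrays were the least alike pair, with r = 0.99288 across genes and 78 genes that differed more than 2-fold between them, against 21 genes in the defeated water pair, 29 in the kososan pair and 16 in the milnacipran pair.

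Part of this spread within groups lay in markers of neighbouring tissue. Ttr, which encodes the transthyretin that the choroid plexus secretes, had log2 intensities of 5.53 and 12.33 on the undefeated water arrays, 12.15 and 6.46 on the defeated water arrays, 12.00 and 12.08 on the kososan arrays and 10.29 and 9.69 on the milnacipran arrays. The mean of the choroid plexus and ependyma list, relative to its mean over the 8 arrays, was -0.78 and 1.01 on the undefeated water arrays and 0.51 and -0.54 on the defeated water arrays. The meninges and fibroblast list had -0.49 and 0.26 on the undefeated water arrays and 0.40 and 0.06 on the defeated water arrays.

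**Figure D1:**
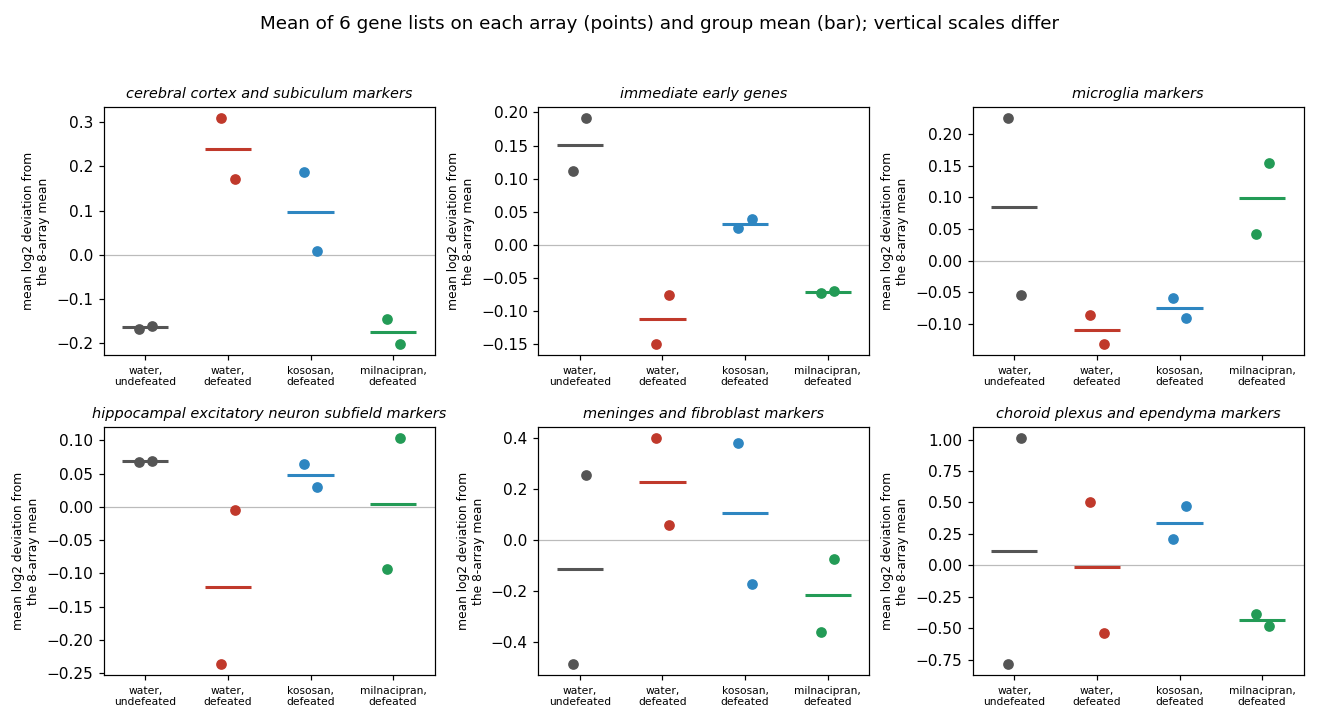
Mean log2 deviation of 6 gene lists from their mean over the 8 arrays, for each array (points) and each group (bars, mean of 2 arrays), with a vertical scale of its own in each panel. The cortex and subiculum list lies at 0.31 and 0.17 on the defeated water arrays and at -0.17 and -0.16 on the undefeated ones, and the choroid plexus list spans -0.78 to 1.01 within the undefeated water pair.

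The first comparison asked how defeat altered the hippocampal transcriptome of mice given water. Among genes above the median level, Unc13c, Ldb2 and Ssty2 had the largest moderated t for higher signal in defeated mice, and Dusp6 the largest for lower signal. Ssty2 lies on the Y chromosome. The second undefeated array stood apart in Eif2s3y, another gene of that chromosome, with a log2 intensity of 3.93 against 7.10 on the first, but not in Ssty2, at 4.54 against 4.40. Unc13c, a synaptic vesicle priming factor, had a log2 fold change of 0.87 ± 0.12 (SE, 2 against 2 arrays), and Etv1, an ETS transcription factor of deep-layer cortical neurons, 1.09 ± 0.18. Resp18, a neuroendocrine secretory protein, had 0.99 ± 0.17, and Ldb2, a LIM-domain binding cofactor, 0.81 ± 0.12. On the lower side stood Dusp6, a phosphatase of the ERK kinases that activity induces, at -0.88 ± 0.13, the immediate early transcription factor Fos at -1.09 ± 0.20 and the calmodulin regulator Pcp4 at -0.48 ± 0.09. None of these passed the adjustment over all genes in limma, with adjusted p = 0.244 for Unc13c and Dusp6, 0.334 for Ldb2, 0.355 for Etv1 and Resp18, 0.356 for Fos and 0.408 for Pcp4.

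The remaining genes named by t were also above the median level. Higher values were found for Ankrd34b at 0.85, Ssty2 at 0.78, the Wnt signalling enhancer Rspo2 at 0.72, Plcxd2 at 0.72, Dusp26 at 0.71, the synaptic adhesion protein Lrrtm3 at 0.59, the synaptic calcium sensor Syt2 at 0.54 and Rnf227 at 0.51 on the log2 scale. Lower values were found for Ppp1r1a, an inhibitor of protein phosphatase 1, at -0.64, the cochaperone Dnajb5 at -0.63, Zswim5 at -0.60, the actin-binding tropomyosin Tpm1 at -0.59, the neuronal differentiation factor Sox11 at -0.50, Rbm24 at -0.49, the non-coding Pantr1 at -0.48, the cyclin Ccnd2 at -0.47 and Vps37b at -0.47. The sign was shared by 1 of 2 probe sets for Zswim5, 3 of 4 for Rbm24 and 2 of 3 for Tpm1. Ctxn3, Amn and Amy1 had the smallest p-values, were chosen after their values were seen and lay below the median level of all genes. Their log2 fold changes were 0.77 ± 0.07 for Ctxn3, 0.91 ± 0.11 for Amn and 0.74 ± 0.09 for Amy1, with adjusted p-values of 0.0565, 0.104 and 0.104.

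Of 17097 genes, 0 passed the limma test for social defeat after adjustment. At an unadjusted p under 0.05 stood 1169 genes, 557 higher and 612 lower, against 855 if no gene differed. The arrays of the 2 groups did not overlap for 33.73% of genes, against 33.3% by chance, and 91 of these genes differed by more than 1.5-fold, 47 higher and 44 lower. Without the second undefeated array 6 genes were called, and without the first 1 gene, where 0 were called with all arrays.

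Among the fixed lists, 7 of 30 were called for social defeat by camera with a preset correlation, 4 toward higher and 3 toward lower values, and 0 were called with an estimated correlation or by fry. Cortex and subiculum markers lay higher, with 15 of 19 measured members above 0 and a mean log2 fold change of 0.40 (adjusted p = 3.73e-06, and adjusted p = 0.265 with an estimated correlation). Adjusted over the list alone, 3 members passed, namely Etv1, the zinc finger gene Tshz2 at 1.19 ± 0.28 and the subcortical projection neuron factor Fezf2 at 0.78 ± 0.22, whereas 0 passed over all genes. Immediate early genes lay lower, with 21 of 29 members below 0 and a mean of -0.26 (adjusted p = 3.39e-05, and adjusted p = 0.265 with an estimated correlation). Adjusted over the list alone, 6 of them passed and 0 passed over all genes: Dusp6, Fos, Junb at -0.72 ± 0.16, Arc at -0.96 ± 0.23, Egr1 at -1.12 ± 0.28 and Egr2 at -0.31 ± 0.08. Fry's test for change in either direction had an adjusted p of 0.00136 for the immediate early genes. This either-direction test was not repeated with arrays left out or grouped otherwise. The camera calls of the cortex and subiculum list and of the immediate early list were kept when any array was left out.

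The other 5 called lists are markers of cell types and of hippocampal subfields. Microglia markers lay lower, with 18 of 21 below 0 and a mean of -0.19 (adjusted p = 6.14e-05, and adjusted p = 0.612 with an estimated correlation), among them the signalling adaptor Tyrobp at -0.46 ± 0.16 and Selplg at -0.25 ± 0.12. Without the first undefeated array their mean was -0.05, the adjusted p 0.286 and the value of Tyrobp -0.19. Endothelial and pericyte markers had 17 of 20 members above 0 and a mean of 0.19 (adjusted p = 1.72e-04, and adjusted p = 0.612 with an estimated correlation), with the tight-junction gene Cldn5 at 0.56 ± 0.19 and the transporter Slco1a4 at 0.33 ± 0.13. Without the first undefeated array the mean was 0.07 and the adjusted p 0.4, and without the second defeated water array Cldn5 was at 0.25. Meninges and fibroblast markers had 15 of 16 members above 0 and a mean of 0.34 (adjusted p = 1.78e-04, and adjusted p = 0.62 with an estimated correlation), with Mgp at 0.72 ± 0.48 and Ptgds at 0.58 ± 0.41. Without the first undefeated array the mean turned to -0.03, Mgp was at 0.08 and Ptgds at -0.01, and without the second Mgp was at 1.36. Without the first defeated water array the mean was 0.17, with an adjusted p of 0.124, and Mgp was at 0.36. Blood cell markers had 10 of 13 members above 0 and a mean of 0.23 (adjusted p = 0.00472, and adjusted p = 0.612 with an estimated correlation), with the haemoglobin gene Hba-a1 at 1.45 ± 0.48 and the neutrophil granule gene Ltf at 0.06 ± 0.09, the 2 brighter members with the largest t. Among its dimmer members, the haem synthesis gene Alas2 at 0.56 ± 0.11 passed over the list alone and not over all genes. S100a9 at 0.19 ± 0.06 and Lyz2 at 0.56 ± 0.24, chosen after their values were seen, did not pass over the list. Markers of excitatory neurons of the hippocampal subfields had 16 of 21 members below 0 and a mean of -0.19 (adjusted p = 0.0279, and adjusted p = 0.612 with an estimated correlation), with Pcp4, which passed over the list alone and not over all genes, and with Rgs14, a signalling regulator of CA2 neurons, at -0.61 ± 0.24. The blood cell call was lost without the first undefeated array (mean 0.16, adjusted p = 0.09) or the first defeated water array (mean 0.18, adjusted p = 0.0701). Hba-a1 was at 0.83 without the first undefeated array and at 2.06 without the second. Rgs14 was at -0.40 without the first undefeated array and at -0.33 without the first defeated water array. The subfield call was lost without either undefeated array (mean -0.19, adjusted p = 0.0577 and 0.163) or without the first defeated water array (mean -0.07, adjusted p = 0.22). With genes above the median level alone, these calls were lost too, while the means were 0.52 for blood cell (adjusted p = 0.0595) and -0.20 for subfield markers (adjusted p = 0.241).

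The lists on the themes that the series names were not called for social defeat. The adjusted camera p was 0.609 for cytokines and their receptors, 0.203 for chemokines and their receptors, 0.952 for dopamine, 0.491 for glutamate, 0.0639 for GABA, 0.491 for acetylcholine and 0.634 for serotonin genes. Fry's test for change in either direction, not repeated with arrays left out or grouped otherwise, had an adjusted p of 0.00554 for acetylcholine genes. Within the glutamate list, Gria4 at 0.37 ± 0.09 and Grm4 at 0.50 ± 0.12 passed the adjustment over the list alone. So did Sox11 in the neurogenesis list, the complement gene C4b at 0.43 ± 0.09 and the neuropeptide receptor Trhr at 0.23 ± 0.05 in their lists, and none of these 5 passed over all genes. The other lists that were not called had adjusted p-values of 0.0518 for astrocytes, 0.129 for heat shock and the unfolded protein response, 0.167 for interneurons, 0.227 for complement and antigen presentation, 0.321 for glucocorticoid-responsive genes, 0.358 for neuropeptides, 0.392 for interferon-stimulated genes, 0.491 for thalamus and habenula, 0.568 for striatum, 0.629 for oligodendrocytes and myelin and for noradrenaline, 0.737 for choroid plexus, 0.787 for neurogenesis, 0.908 for oxidative phosphorylation and for neurotrophins, and 0.952 for the circadian clock.

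**Figure D2:**
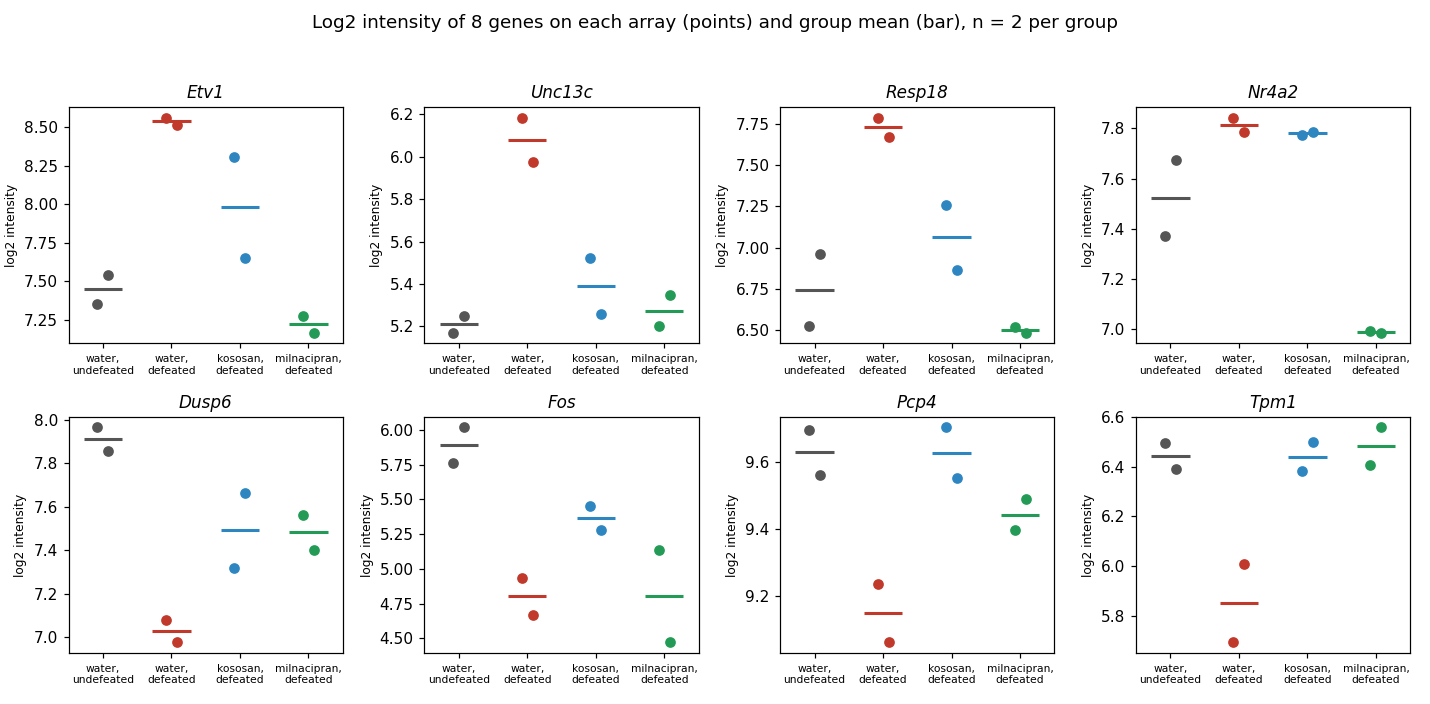
Log2 intensity of 8 genes on each array (points) and the mean of each group of 2 arrays (bars), with a vertical scale of its own in each panel. Etv1, Unc13c and Resp18 are highest on the defeated water arrays, Dusp6 and Pcp4 are lowest there, and Nr4a2 is lowest on the milnacipran arrays, at a mean of 6.99.

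The second comparison set kososan against water in defeated mice. Among genes above the median level, the largest t values for higher signal belonged to Cacng5, a regulatory subunit of AMPA receptors, at 0.59 ± 0.10, Clmn at 0.48 ± 0.09, Pcp4 at 0.48 ± 0.09, Tpm1 at 0.59 ± 0.12, Ly6e at 0.78 ± 0.17 and the axon guidance receptor Robo1 at 0.60 ± 0.14 (log2 fold change ± SE, 2 against 2 arrays). Of the probe sets for Cacng5, 1 of 2 had this sign, and of those for Clmn 4 of 6. Further genes with higher values were Gpc1 at 0.66, Prdm8 at 0.59, the neuropeptide gene Cck at 0.58, the sphingomyelinase Smpd3 at 0.47, Pgd of the pentose phosphate pathway at 0.41 and the translocon subunit Sec61a1 at 0.35. On the lower side stood Unc13c at -0.69 ± 0.12, Egfem1 at -0.47 ± 0.09, Ldb2 at -0.56 ± 0.12, Itih3 at -0.72 ± 0.17, Erdr1 at -0.68 ± 0.17 and Resp18 at -0.67 ± 0.17. They were followed by Dusp26 at -0.50, Dzank1 at -0.44, Lrrtm3 at -0.42, Smc5 at -0.38, Syt2 at -0.35 and Zer1 at -0.33. The adjusted p of each of these 24 genes was 0.938. Ctxn3, Amn and Amy1, chosen after their values were seen, had -0.52 ± 0.07, -0.76 ± 0.11 and -0.55 ± 0.09, with adjusted p-values of 0.664, 0.664 and 0.776.

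Of 17097 genes, 0 passed for kososan in limma, and 762 had an unadjusted p under 0.05, 449 higher and 313 lower, against 855 if no gene differed. The arrays did not overlap for 35.99% of genes, against 33.3% by chance. By camera 7 of 30 lists were called for kososan, and 0 with an estimated correlation or by fry. The adjusted p with an estimated correlation was 0.731 for each of the 7. Markers of excitatory neurons of the hippocampal subfields had 15 of 21 members above 0 and a mean of 0.17 (adjusted p = 0.0167), with Pcp4, the only member of a called list to pass over its list alone, and the pentraxin Nptx1 at 0.46 ± 0.13. Heat shock and unfolded protein response genes had 17 of 20 above 0 and a mean of 0.14 (adjusted p = 0.0213), with the chaperones Hsph1 at 0.34 ± 0.12 and Hspa1b at 0.69 ± 0.30. Immediate early genes had 19 of 29 above 0 and a mean of 0.14 (adjusted p = 0.0377), with Dusp6 at 0.46 ± 0.13 and Fos at 0.56 ± 0.20. Astrocyte markers had 14 of 17 below 0 and a mean of -0.12 (adjusted p = 0.0167), with the glycolytic enzyme Aldoc at -0.26 ± 0.07, whereas the acute-phase gene Serpina3n had 0.36 ± 0.15. Cortex and subiculum markers had 12 of 19 below 0 and a mean of -0.14 (adjusted p = 0.0377), with Etv1 at -0.56 ± 0.18 and Tshz2 at -0.77 ± 0.28. Blood cell markers had 11 of 13 below 0 and a mean of -0.14 (adjusted p = 0.0295), with Hba-a1 at -0.79 ± 0.48 and Ltf at -0.06 ± 0.09. Chemokines and their receptors had 28 of 40 below 0 and a mean of -0.03 (adjusted p = 0.0377), although the brighter members with the largest t, the neuronal chemokine Cx3cl1 at 0.44 ± 0.17 and the scavenger receptor Ackr3 at 0.32 ± 0.15, lay above 0. Without the first defeated water array the means were -0.07 for astrocyte (adjusted p = 0.141), 0.05 for subfield (adjusted p = 0.178), -0.10 for blood cell (adjusted p = 0.197), 0.11 for immediate early (adjusted p = 0.197), -0.01 for chemokine (adjusted p = 0.403) and -0.07 for cortex and subiculum genes (adjusted p = 0.373), and Cx3cl1 was at 0.14. Without the second kososan array they were 0.03 for heat shock (adjusted p = 0.877), -0.04 for astrocyte (adjusted p = 0.52), -0.06 for blood cell (adjusted p = 0.186), 0.14 for immediate early (adjusted p = 0.105), -0.01 for chemokine (adjusted p = 0.254) and -0.05 for cortex and subiculum genes (adjusted p = 0.526). Hba-a1 was then at -0.09, Etv1 at -0.23, Tshz2 at -0.45, Hspa1b at 0.44, Hsph1 at 0.21, Dusp6 at 0.29 and Ackr3 at 0.13. When the first defeated water array was left out, Hspa1b was at 0.35, Hsph1 at 0.20, Serpina3n at 0.15, Nptx1 at 0.25 and Ackr3 at 0.18. Without the second defeated water array heat shock genes had a mean of 0.11 (adjusted p = 0.206) and immediate early genes 0.18 (adjusted p = 0.0624). Without either undefeated array the cortex and subiculum mean stayed at -0.14 (adjusted p = 0.0549 and 0.0551). Thus each of the 7 calls was lost with at least 1 array left out, and the number of called lists was 2 without the first defeated water array, 3 without the second kososan array and 11 without the first. With genes above the median level alone, 1 list was called, and with the mean of a gene's probe sets 3 lists. With the replicate number as a block, the cortex and subiculum call was lost (adjusted p = 0.0527). With a second quantile normalization the chemokine call was lost (mean -0.02, adjusted p = 0.156).

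The other lists on the themes that the series names were not called for kososan. The adjusted camera p was 0.269 for cytokines and their receptors, 0.928 for dopamine, 0.871 for glutamate, 0.148 for GABA, 0.986 for acetylcholine and 0.737 for serotonin genes. The noradrenaline list, which the series does not name, had an adjusted p of 0.576, with 5 of 6 members below 0.

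The third comparison set milnacipran against water in defeated mice. Among genes above the median level, the 3 largest absolute t values belonged to Nr4a2, Resp18 and Etv1, all with lower signal. Nr4a2, an orphan nuclear receptor, had -0.82 ± 0.11 (log2 fold change ± SE, 2 against 2 arrays), Resp18 -1.23 ± 0.17 and Etv1 -1.31 ± 0.18. Unc13c had -0.81 ± 0.12, Lrrtm3 -0.73 ± 0.11, Dusp26 -0.78 ± 0.13, Ldb2 -0.77 ± 0.12 and Syt2 -0.55 ± 0.09. The adjusted p was 0.158 for Nr4a2 and Resp18, 0.177 for Etv1, 0.205 for Unc13c and Lrrtm3 and 0.265 for Dusp26, Ldb2 and Syt2. The others were Nap1l5 at -0.64, the tissue plasminogen activator gene Plat at -0.59, the axonal adhesion protein Cntn4 at -0.56 and Impact at -0.47. Higher values were found for Abracl at 0.80, the desmosomal Pkp2 at 0.75, the potassium channel Kcnk2 at 0.67, Tpm1 at 0.63, Cck at 0.61, the postsynaptic scaffold Homer2 at 0.57, Smpd3 at 0.47, the vesicular glutamate transporter Slc17a7 at 0.46, Ppp1r1a at 0.46, the microglial purinergic receptor P2ry12 at 0.44, B4galt2 at 0.39 and Lsm11 at 0.37. The sign was shared by 4 of 5 probe sets for Nr4a2 and 2 of 3 for Tpm1. In a fit with the cortex and subiculum mean as a covariate, added after the data had been seen, Abracl turned to -0.14, Cck to -0.14, Kcnk2 to -0.0054 and Homer2 to -0.0042. Ctxn3, Amn and Amy1, chosen after their values were seen, had -0.78 ± 0.07, -0.96 ± 0.11 and -0.73 ± 0.09, with adjusted p-values of 0.0506, 0.0841 and 0.0841.

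Of 17097 genes, 0 passed for milnacipran in limma, and 970 had an unadjusted p under 0.05, 448 higher and 522 lower, against 855 if no gene differed. The arrays did not overlap for 36.07% of genes, against 33.3% by chance, and 115 of these differed by more than 1.5-fold, 38 higher and 77 lower. A fit of only the 4 arrays compared called 7 genes, among them Etv1, Resp18, Amn and Ctxn3. Leaving out either undefeated array, which is not part of this contrast but enters the estimate of spread, gave 6 genes, and leaving out either kososan array gave 2.

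By camera 8 of 30 lists were called for milnacipran, and 0 with an estimated correlation or by fry. Microglia markers had 21 of 21 members above 0 and a mean of 0.21 (adjusted p = 6.2e-07, and adjusted p = 0.641 with an estimated correlation), with P2ry12, which passed over its list alone but not over all genes, and P2ry13 at 0.32 ± 0.14. Cortex and subiculum markers had 12 of 19 below 0 and a mean of -0.41 (adjusted p = 1.43e-05, and adjusted p = 0.641 with an estimated correlation). Adjusted over the list alone, 5 of its members passed and 0 over all genes: Nr4a2, Etv1, Tshz2 at -1.23 ± 0.28, Fezf2 at -0.86 ± 0.22 and the neuropeptide gene Nts at -2.08 ± 0.54. The calls of these 2 lists were kept when any array was left out. Meninges and fibroblast markers had 15 of 16 below 0 and a mean of -0.45 (adjusted p = 2.93e-05, and adjusted p = 0.725 with an estimated correlation), with Ptgds at -0.95 ± 0.41 and the proteoglycan Dcn at -1.35 ± 0.75. Choroid plexus and ependyma markers had 23 of 24 below 0 and a mean of -0.42 (adjusted p = 0.00157, and adjusted p = 0.869 with an estimated correlation), with Igf2 at -1.32 ± 0.79 and Col8a1 at -0.38 ± 0.26. Without the first defeated water array the choroid plexus mean turned to 0.10, Igf2 was at -0.65 and Col8a1 at -0.04, and the meninges mean was -0.28 with an adjusted p of 0.107. Endothelial and pericyte markers had 17 of 20 below 0 and a mean of -0.17 (adjusted p = 0.00279, and adjusted p = 0.725 with an estimated correlation), with Cldn5 at -0.65 ± 0.19 and Vtn at -0.74 ± 0.29. Cldn5 was at -0.34 without the second defeated water array. Ptgds was at -0.46 and Dcn at -0.88 without the first milnacipran array.

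Neuronal and hormone-responsive lists made up the rest. Subfield markers of excitatory neurons had 14 of 21 above 0 and a mean of 0.13 (adjusted p = 0.0144, and adjusted p = 0.641 with an estimated correlation), with Bok at 0.87 ± 0.22, whereas Calb2, which encodes the calcium-binding calretinin, had -1.03 ± 0.32. GABA receptor and synthesis genes had 10 of 19 below 0, a mean of -0.14 and a median of -0.0027 (adjusted p = 0.0157, and adjusted p = 0.641 with an estimated correlation), with the vesicular GABA transporter Slc32a1 at -0.52 ± 0.16 and the receptor subunit Gabrg1 at -0.44 ± 0.15. Of the probe sets for Slc32a1, 1 of 2 had this sign. Glucocorticoid-responsive genes had 17 of 25 above 0 and a mean of 0.10 (adjusted p = 0.028, and adjusted p = 0.641 with an estimated correlation), with the transcription factor Klf9 at 0.28 ± 0.08 and the kinase Sgk1 at 0.66 ± 0.22. Of the probe sets for Klf9, 4 of 5 had this sign. Bok was at 0.56 without the second milnacipran array. Without the second defeated water array the endothelial, GABA and glucocorticoid calls were lost (adjusted p = 0.247, 0.216 and 0.247), while the means were -0.13, -0.12 and 0.10. Without the first milnacipran array the glucocorticoid mean was 0.05 (adjusted p = 0.568) and Sgk1 was at 0.26. The subfield mean was 0.03 without the second milnacipran array (adjusted p = 0.326) and 0.01 without the first defeated water array (adjusted p = 0.193). In the lists that were not called, Slc17a7, Gria4 at -0.37 ± 0.09, Grik1 at -0.86 ± 0.23, Grm8 at -0.33 ± 0.09, Alas2 at -0.47 ± 0.11, Trhr at -0.23 ± 0.05 and Cck passed over their list alone and not over all genes. So did Nr4a2 in the list of immediate early genes. With genes above the median level alone, the means were -0.53 for choroid plexus (adjusted p = 0.0623) and 0.09 for subfield markers (adjusted p = 0.107). With the mean of a gene's probe sets the GABA mean was -0.09 (adjusted p = 0.106). Among the themes that the series names, the adjusted camera p for milnacipran was 0.469 for cytokines, 0.788 for chemokines, 0.745 for dopamine, 0.5 for glutamate, 0.983 for acetylcholine and 0.481 for serotonin genes. Noradrenaline genes, which the series does not name, had 5 of 6 measured members above 0 and a mean of 0.09 with milnacipran (adjusted p = 0.206). Fry's test for change in either direction, not repeated with arrays left out or grouped otherwise, had an adjusted p of 0.00969 for acetylcholine genes.

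Against each other, the treatments differed in 0 of 17097 genes in limma, with 557 at an unadjusted p under 0.05. The smallest adjusted p was 0.875, for Nr4a2, chosen after its value was seen, which was higher with kososan by 0.79 on the log2 scale. By camera 11 of 30 lists were called for kososan against milnacipran and 0 with an estimated correlation (smallest adjusted p = 0.453). Microglia markers had 20 of 21 members lower with kososan (mean -0.17, adjusted p = 1.31e-06, and adjusted p = 0.459 with an estimated correlation), heat shock genes 18 of 20 higher (mean 0.15, adjusted p = 9.07e-05, and adjusted p = 0.453 with an estimated correlation) and choroid plexus markers 23 of 24 higher (mean 0.78, adjusted p = 3.24e-06, and adjusted p = 0.671 with an estimated correlation). Noradrenaline genes had 5 of 6 members lower with kososan (mean -0.11, adjusted p = 0.00776, and adjusted p = 0.453 with an estimated correlation), and glucocorticoid-responsive genes 18 of 25 lower (mean -0.07, adjusted p = 0.00776, and adjusted p = 0.453 with an estimated correlation). Cortex and subiculum markers had 14 of 19 members higher with kososan (mean 0.27, adjusted p = 0.00468, and adjusted p = 0.453 with an estimated correlation), interneuron markers 17 of 24 (mean 0.13, adjusted p = 0.0114, and adjusted p = 0.453 with an estimated correlation) and neurotrophins 14 of 18 (mean 0.23, adjusted p = 0.0157, and adjusted p = 0.453 with an estimated correlation). Also higher were 15 of 16 meninges markers (mean 0.32, adjusted p = 0.00468), 17 of 20 thalamus and habenula markers (mean 0.32, adjusted p = 0.00468) and 16 of 20 endothelial markers (mean 0.16, adjusted p = 0.00658), each with an adjusted p = 0.671 with an estimated correlation. The array means overlapped between the treatments for meninges markers, at 0.38 and -0.17 with kososan and -0.36 and -0.07 with milnacipran. They also overlapped for thalamus, heat shock and glucocorticoid-responsive genes, and not for the other lists called here.

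Against undefeated mice 0 genes passed for kososan, with 717 at an unadjusted p under 0.05, and 0 for milnacipran, with 842. Immediate early genes were below the undefeated level in both treated groups, with 19 of 29 members lower and a mean of -0.12 for kososan (adjusted p = 0.00845, and adjusted p = 0.543 with an estimated correlation) and 23 of 29 lower and a mean of -0.22 for milnacipran (adjusted p = 6.21e-06, and adjusted p = 0.355 with an estimated correlation). Cortex and subiculum markers had 16 of 19 members above the undefeated level with kososan (mean 0.26, adjusted p = 9.76e-04, and adjusted p = 0.543 with an estimated correlation), and interneuron markers 19 of 24 (mean 0.11, adjusted p = 0.00154, and adjusted p = 0.439 with an estimated correlation). The other lists called for kososan against undefeated mice were 3. They were microglia markers, 19 of 21 lower (mean -0.16, adjusted p = 3.82e-04), endothelial markers, 17 of 20 higher (mean 0.18, adjusted p = 3.82e-04), and meninges markers, 16 of 16 higher (mean 0.22, adjusted p = 0.0126), each with an adjusted p = 0.849 with an estimated correlation. The array means overlapped for meninges markers (0.38 and -0.17 with kososan, -0.49 and 0.26 undefeated) and endothelial markers (0.169 and -0.0002 with kososan, -0.215 and 0.021 undefeated). For microglia markers the kososan arrays had -0.059 and -0.091, close to the second undefeated array at -0.055, while the first had 0.225. These 3 differences thus rest largely on the first undefeated array. The other lists called for milnacipran against undefeated mice were choroid plexus markers, 22 of 24 lower (mean -0.55, adjusted p = 3.26e-04), and heat shock genes, 18 of 20 lower (mean -0.14, adjusted p = 0.00888), each with an adjusted p = 0.955 with an estimated correlation. The choroid plexus means of the milnacipran arrays, -0.39 and -0.48, lay between those of the undefeated arrays, -0.78 and 1.01. That difference thus rests on the second undefeated array. Noradrenaline genes had 6 of 6 members above the undefeated level with milnacipran and a mean of 0.11 (adjusted p = 0.0586). The list calls between the treatments and against undefeated mice were not repeated with arrays left out. Over all groups, the moderated F test called 0 genes, with 748 at an unadjusted p under 0.05 and a smallest adjusted p of 0.152.

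Finally, the effects were compared across genes, which are not independent replicates. The kososan and milnacipran effects had r = 0.64 over 17097 genes, where unchanged groups against the same controls gave 0.504 with independent genes. The covariance was 0.0116 against a simulated 0.00860. Against the effect of defeat, r was -0.64 for kososan and -0.63 for milnacipran, where unchanged groups gave -0.495 and -0.502, and the covariances were -0.0117 and -0.0128 against simulated values of -0.00839 and -0.00854. When the simulation kept the gene-to-gene correlation of the real arrays, 95% of the draws for kososan and milnacipran lay between -0.695 and 0.966, and those against defeat between -0.962 and 0.696 for kososan and between -0.967 and 0.675 for milnacipran. All 3 observed values lay inside these ranges. The medians of these draws were 0.561, -0.563 and -0.536, in the same order. The 2 control arrays could not be divided into sets of 2, so part of the excess over the simulated values may come from the shared controls.

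**Figure D3:**
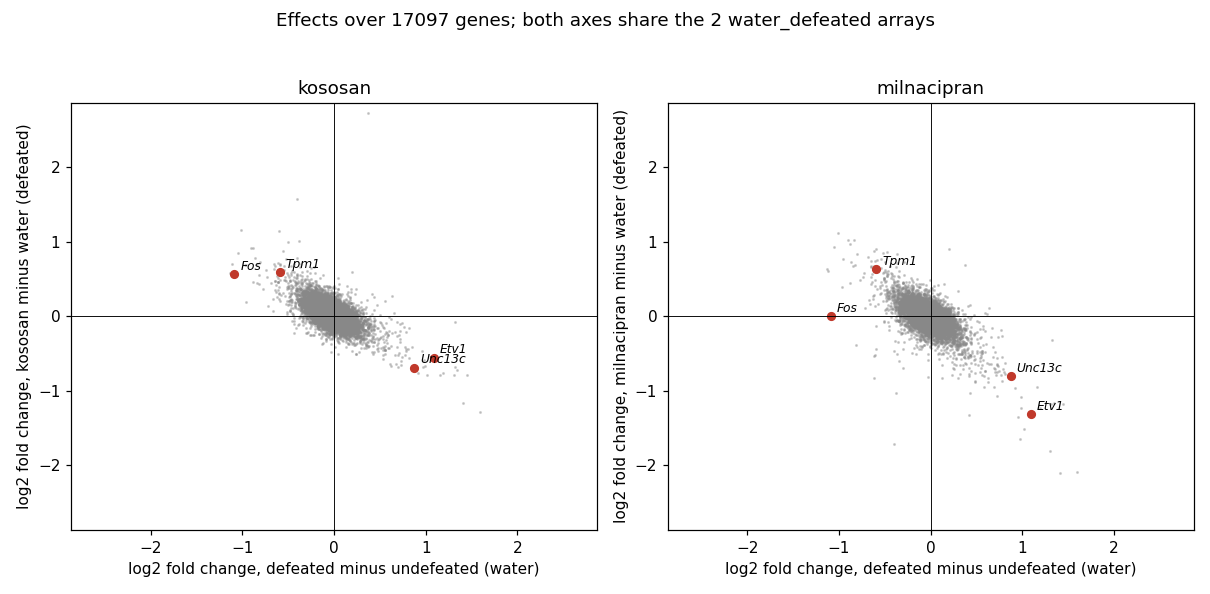
Log2 fold change with kososan (left) and milnacipran (right) against the log2 fold change with defeat, 1 point for each of 17097 genes, with 4 named genes in red. Genes such as Etv1 and Unc13c lie above 0 for defeat and below 0 for both treatments, and the slope across all genes, with r = -0.64 and r = -0.63, includes the part that the shared defeated water arrays produce.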

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

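The fits with a list mean as a covariate were chosen after the data had been seen. With 0 genes called in each comparison, the robust prior called 1 gene for social defeat and 3 for milnacipran, a second quantile normalization 1 and 1, centring on array medians 1 and 1, array weights 1 for milnacipran, the 4 arrays compared alone 7 for milnacipran, and the choroid plexus covariate 1 for social defeat. Tested singly, all probe sets gave 3 calls for social defeat and 1 for kososan against undefeated mice. The cause of these calls was not tested. Leaving out each array in turn gave 0 to 6 genes for social defeat, 0 to 0 for kososan, 0 to 6 for milnacipran, 0 to 0 for kososan against milnacipran, 0 to 4 for kososan against undefeated, 0 to 2 for milnacipran against undefeated and 0 to 4 for any group. A prior without a trend, the mean of a gene's probe sets and the level filter called 0 genes in each comparison. The table deposited beside the first holds the same values and moves nothing.

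The 7, 7 and 8 lists called for social defeat, kososan and milnacipran became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 by fry. For kososan, 1 list was called with genes above the median level and 3 with the mean of a gene's probe sets. Of the 22 list calls, the level filter ended 10, among them 2 for social defeat (blood cells and subfields) and 2 for milnacipran (choroid plexus and subfields). The mean of probe sets ended 5, among them GABA for milnacipran, and a second quantile normalization ended 1, chemokines for kososan. With an array left out, the counts ran from 5 to 10, from 2 to 11 and from 5 to 11. Without the first undefeated array the meninges mean for social defeat turned to -0.0264 (up to 0.714 without the second), without the first defeated water array the choroid plexus mean for milnacipran turned to 0.1 (down to -0.942 without the second), and with genes above the median level the chemokine mean for kososan turned to 0.00484. The correlations of effects ran from 0.4207 to 0.814 for kososan and milnacipran, from -0.8006 to -0.4898 for kososan against defeat and from -0.7926 to -0.3854 for milnacipran against defeat when an array was left out.

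The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.296, -0.142, 0.191, 0.11, -0.0139 and -0.365 over the 6 pairs of groups. With the replicate number as a block, 0 genes were called in each comparison and 9, 7 and 8 lists for social defeat, kososan and milnacipran. The block ended 1 of the 22 list calls, that of cortex and subiculum markers for kososan (adjusted p = 0.0527).

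Of 1980 values of named genes under the alternatives fixed before the data were seen, 1977 kept their direction. For the genes named by t this was partly fixed in advance, since their arrays had to lie apart between the groups. Leaving out an array could then not turn their sign. With an array left out, 32 of the 117 named results shrank by over 1.5 times or turned. The exceptions in direction were Ptgds for social defeat at -0.01021 without the first undefeated array (1.17 without the second), and Ltf without the first defeated water array at -0.03223 for social defeat and 0.03203 for kososan (0.1551 and -0.1553 without the second). With the cortex and subiculum covariate, which has 90.1% of its variance between the groups and leaves 3 residual degrees of freedom, more genes turned. For social defeat these were Slco1a4 (-0.02078), Mgp (-1.55), Ptgds (-0.3238), Hba-a1 (-0.3957), Ltf (-0.06246) and Rgs14 (0.5353). For milnacipran they were Abracl (-0.1382), Kcnk2 (-0.005356), Homer2 (-0.004216), Cck (-0.1363), Dcn (1.53), Col8a1 (0.235), Vtn (0.8327), Bok (-0.1823) and Gabrg1 (0.3187). The cause was not tested. Genes near the lowest intensities carry little signal over background, which limits what can be said of Ctxn3, Amn and Amy1.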

Other observations

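All tests in this part were chosen after the results had been seen. The adult neurogenesis list was not called for social defeat, kososan or milnacipran. Its array means were 0.02 and 0.03 for undefeated water, 0.01 and -0.01 for defeated water, 0.04 and 0.03 for kososan and -0.07 and -0.04 for milnacipran. Of the 105 ways to divide the 8 arrays into 4 pairs, 2 placed as large a share of this list's variance between the pairs as the real groups, and the exact permutation p of 0.019 became 0.286 after adjustment over the 30 lists. The cortex and subiculum list, with 6 of 105 divisions as large, had an exact permutation p of 0.0571, which became 0.571 after adjustment over the 30 lists.

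The first pattern is a set of 213 genes with an unadjusted p under 0.05 both for higher signal with defeat and for lower signal with milnacipran, among them Etv1, Unc13c, Resp18 and Ldb2, while 153 genes had the opposite directions. Of 100 assignments of the 8 arrays to the groups, the real one included, 7 gave as many such genes, with a highest other count of 301, so a chance arrangement of the arrays is not excluded. A candidate explanation is a larger share of cortex or subiculum in the defeated water dissections: within the groups, the mean of the 206 pattern genes outside the cortex and subiculum list moved with that list's mean, and the slope predicts 80% of the mean difference of 0.40 between the water groups (59.2% to 91.1% with a group left out). That slope rests on 4 differences between 2 arrays, and mostly on the defeated water and kososan pairs, where the list differed most. On the undefeated arrays the list hardly moved, at -0.168 and -0.16. Whatever else varied with the list would enter the slope. The set also holds members of other lists, such as the thalamus marker Tcf7l2 (1.02 with defeat, -1.51 with milnacipran) and the GABA gene Gad2 (0.42 and -0.51). Cortex or subiculum is thus not singled out. An effect of defeat that treatment opposes stays open, and was not tested apart from tissue share.

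The second pattern is the mean of the immediate early genes, at -0.15 and -0.07 on the defeated water arrays and at -0.07 and -0.07 with milnacipran, against 0.11 and 0.19 on the undefeated arrays and 0.02 and 0.04 with kososan. The real grouping had the highest share of variance between pairs of all 105 divisions (93.1% against 92.9% for the next), so 1 of 105 was as large, an exact p of 0.00952 that is the smallest possible here and 0.286 after adjustment over 30 lists. The list was picked after its values were seen, and the measure takes in any difference among the groups, so chance is not excluded. A larger share of cortex or subiculum could account for 34.2% of the difference from the slope within groups, with a range from 8.49% to 66.5% when a group is left out, which is too wide to decide. A biological effect of defeat stays open and was not tested.

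The third pattern is the spread of choroid plexus genes within groups. Of 44 differences between the 2 arrays of a group, over 11 bright members other than Ttr, 40 (90.9%) had the sign of Ttr's difference. Choroid plexus tissue attached to the dissected hippocampus in varying amounts would give this, as would any other cause that moves these genes together. The members vary together over only 4 pairs of arrays, so the 44 are not independent observations. In the kososan pair 10 of 11 shared the sign of a Ttr difference of only -0.08. The 2 arrays of a group share condition and treatment, so these alone do not give a spread within a group. As to differences between groups, 81 of the 105 divisions placed as large a share of the list's variance between pairs. An effect on top of the spread cannot be told apart with 2 arrays per group. The serotonin receptor gene Htr2c, which choroid plexus expresses strongly, had r = 0.747 with the choroid plexus mean over 8 arrays (exact permutation p = 0.0375) and a Spearman rho of 0.69 (exact permutation p = 0.0694). Adjusted over the 16 serotonin genes examined these became 0.6 and 0.555, r was 0.555 without the 2 farthest arrays, and they moved together in the 2 groups whose arrays differed most in the list (by -1.79 and 1.04) and apart in the 2 that differed little (by -0.27 and 0.09), so the relation did not pass the adjustment and is left open. Nor was it particular to Htr2c. Htr2b had a lower r of 0.663 but a higher Spearman rho of 0.786 (exact permutation p = 0.0279, adjusted p = 0.446). It moved with the list in 4 groups, and its r was 0.276 without the 2 farthest arrays.

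Counts of nominal differences and of called lists were also reached by other arrangements of the arrays. Of 100 assignments, the real one included, 10 gave as many genes at p under 0.05 as the 1169 for social defeat (highest other 1885), 50 as many as the 762 for kososan (highest other 1403) and 28 as many as the 970 for milnacipran (highest other 1659). For called lists, 35 gave at least 7 for social defeat (highest other 13), 48 at least 7 for kososan (highest other 15) and 26 at least 8 for milnacipran (highest other 16), so chance is not excluded for any of these counts. The 99 other assignments called a median of 5, 6 and 6 lists in the 3 comparisons, and 94, 96 and 97 of them called at least 1. A list call by camera with a preset correlation was thus common under other arrangements of the arrays. Of the 99 other assignments, 9, 14 and 7 called any gene in the 3 comparisons, with a median of 0 and a maximum of 16, 24 and 12, where the real groups called 0. Which arrays these few assignments set together was not examined.

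The second undefeated array stood apart from the first in some genes of the Y chromosome, chosen after their values were seen. Its log2 intensities were 3.93 for Eif2s3y, 4.78 for Kdm5d and 3.56 for Uty, against 7.10, 6.45 and 5.0 on the first undefeated array, while Xist had 5.23 and 5.16. Over the 6 arrays of defeated mice Eif2s3y lay between 6.18 and 6.91.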
